A study of Mus musculus with 10 samples.

How the data were processed

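Polyadenylated RNA was sequenced from 10 libraries of a mouse cell line that the labels call iKCs. Cells carried 1 of 4 vectors and were sorted on the fluorescent marker mOrange and on viability. The groups were miR-342-3p overexpression (n = 3), a mutated miR-342-3p control (n = 2), a miR-342-3p sponge (n = 3) and a scramble sponge control (n = 2). The group and the replicate number of each library came from its title, which calls the libraries biological replicates; how the cultures were separated is not given in the sources used here, so p-values measure the spread between these libraries.

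The deposited table holds whole-number counts of reads per gene, with no normalization. Per the file headers, the authors counted with featureCounts 2.0.1 against the GENCODE vM30 annotation, by gene name. Per the same headers, read pairs were counted with both ends mapped and without chimeric pairs, with a minimum overlap of 10 bases and with strand setting 0. Strand was therefore not used, so reads of a gene and of an overlapping or antisense partner cannot be told apart. Per the submitters' processing notes, FastQC 0.11.6, Trimmomatic, STAR 2.7.6a and Subread were used, and the notes name the build GRCm38. The vM30 annotation of the header belongs to a later build, so coordinates are given as the deposited file states them, without a build of their own. The counting command of the header names 12 libraries; 10 are analysed here.

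The deposited lines have 15 fields under 16 column names, because the counts of sponge replicate 3 and of the next scramble library stand in 1 field without a separator. Each joined number was split at the place most likely under a negative binomial distribution with a dispersion of 0.1. The expectation was each gene's share of all reads in the 8 intact libraries, whatever their group. A gene was kept where the best split was at least 100 times likelier than the next, and 51 of 55866 genes were left out. The same split was tested on 22 ordered pairs of intact libraries joined on purpose. The lowest share of genes recovered in a pair was 99.8998%, and at most 7 genes with a mean count of at least 10 were wrong after the filter. The last field of each line was taken as the other scramble library, from the order of the header, so its group is certain and its replicate number is not.

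Gene counts were tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM factors, expression filter by group) in R 4.3.3. All 10 libraries entered 1 fit with 6 residual degrees of freedom, and 15767 genes were tested. Adjusted p-values are Benjamini-Hochberg values over those genes, with a threshold of 0.05, and a standard error (SE) is the log2 fold change divided by the square root of F. Levels are in CPM, computed here with TMM factors. The contrasts were overexpression minus mutated control, sponge minus scramble, mutated control minus scramble, and the difference of the first 2. The 18 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01. An estimated correlation and fry were run beside it. The tests of seed-site genes were adjusted over the 2 vector comparisons.

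Seed sites were searched in the longest annotated 3′ UTR of each gene in GENCODE vM21 (GRCm38), which gave UTRs for 20799 genes of the table, 20427 by symbol and 372 by an older symbol. The main set held genes with an 8mer or 7mer-m8 site of miR-342-3p. Each 7-mer was also ranked by its coefficient on the log2 fold change, with log UTR length and GC content as covariates. A wider 7-mer model was added after seeing the data. It has squared terms of length and GC content, log2 CPM, fold changes limited to a size of 2, and a ranking by z of 7-mers found in at least 50 genes.

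Named genes followed a rule fixed before the data were examined. Slc7a11 and Evl, the host gene of the microRNA, were always named. The rule further took the 10 largest rises and falls among called genes with a mean log2 CPM of at least 2, groups that do not overlap and a standard symbol. Where none passed, it took the 5 genes with the smallest p. It also took up to 3 genes with the smallest p per list and up to 5 genes with an 8mer site in the direction of the perturbation. The comparison of the controls and that of the 2 effects took 5 per direction.

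The functions were tested on simulated counts with 200 changed genes. For the overexpression comparison (15513 genes), 89.3% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes were recovered. For the sponge comparison (15521 genes), 89.3% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes were recovered. False calls made up 7.18% and 5.88% of the calls. The changed genes had a mean log2 CPM of at least 2, and each gene was drawn separately around 1 mean for all libraries. Differences between libraries that many genes share were therefore absent, so these shares need not hold for the deposited counts. Alternatives were DESeq2 1.42.0, limma-voom, other factors and filters, replicate blocks and leaving out each library. A surrogate variable (sva 3.50.0), other controls, a test of each group against the mean of the scramble and sponge groups, thinning to equal totals and further exclusions were added after seeing the data.

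Library totals ranged from 25713110 to 59260772 counts. A count of 0 allows up to 3 counts, which is 0.0506 to 0.117 CPM depending on the library and covers counting error only. No pair of replicates was a duplicate: chi-square per degree of freedom was between 4.40 and 43.0.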

Results

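Bulk RNA sequencing compared sorted mOrange-positive iKCs, a mouse cell line, that carried a vector for miR-342-3p overexpression, a sponge for the same microRNA, or 1 of 2 control vectors. A sponge is a transcript with binding sites that sequester a microRNA. The series title concerns miR-342 and inflammatory features of macrophages in liver metastases. The total was 59260772, 42867716 and 25713110 counts for overexpression replicates 1, 2 and 3, and 47004925 and 41334252 for the mutated control. It was 44969478, 50982195 and 43089643 for the sponge and 33857569 and 57708592 for the scramble control. Each control group had 2 libraries.

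Reads over the Mir342 hairpin checked the labels. Mir342 lies on chromosome 12 from 108624879 to 108624977 on the plus strand, inside its host gene Evl (108520979 to 108654775). It had 9.64 ± 1.54 CPM (SD, n = 3) with overexpression and 3.04 ± 0.256 CPM (SD, n = 2) in the mutated control. All 5 sponge and scramble libraries had 0 reads, which allows at most 0.0886 CPM in the shallowest of them. The hairpin reads therefore do not tell the sponge group from the scramble group. Mir342 was 3.17-fold higher with overexpression than in the mutated control (edgeR adjusted p = 0.0123). The libraries were made from polyadenylated RNA, so these reads stand for transcripts that contain the hairpin and not for the mature microRNA. The sequence of the mutated hairpin is not given in the sources used here. How well its reads align to this locus is therefore not known, and the fold against the mutated control depends on it. Evl had 85.5 ± 6.4 CPM (SD, n = 3) with overexpression and 87.3 ± 4.87 CPM (SD, n = 2) in the mutated control (log2 fold change −0.03, SE 0.08).

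**Figure D1:**
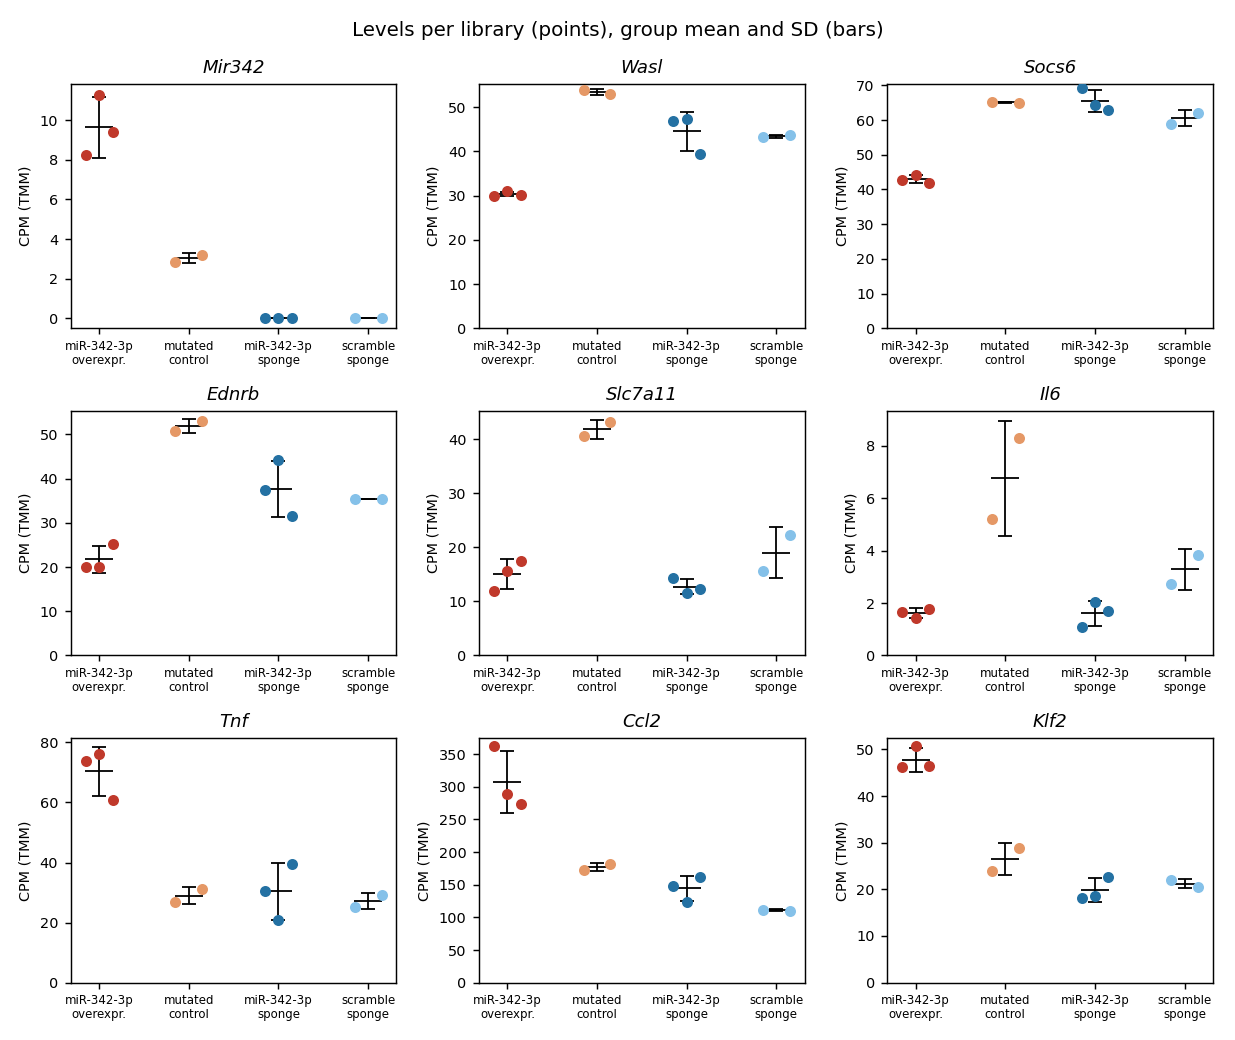
CPM per library (points) with the group mean and SD (bars) for the hairpin and 8 genes, in the 4 vector groups on the x axis. Slc7a11 and Il6 are highest in the mutated control, whereas Wasl, Socs6 and Ednrb are lowest, and Tnf, Ccl2 and Klf2 highest, in the overexpression libraries.

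Overexpression against the mutated control asked what miR-342-3p changes, and against this control inflammatory genes changed in both directions. The cytokine Tnf was 2.43-fold higher (70.3 ± 8.24 CPM, SD, n = 3, against 29.0 ± 2.83 CPM, SD, n = 2). The monocyte chemokines Ccl2 and Ccl7 were 1.74-fold and 2.04-fold higher, and the transcription factor Klf2 was 1.81-fold higher. The cytokine Il6 fell by 2.06 on the log2 scale (SE 0.26) and the costimulatory molecule Cd86 fell by 0.86 (SE 0.11). Il6 was at a low level (1.63 ± 0.187 CPM, SD, n = 3, against 6.75 ± 2.18 CPM, SD, n = 2). Slc7a11, the cystine transporter subunit, was 2.81-fold lower, with 41.9 ± 1.81 CPM (SD, n = 2) in the mutated control (edgeR adjusted p = 0.00632). Ednrb, an endothelin receptor, was 2.40-fold lower, Wasl, an actin regulator, 1.76-fold lower, and Socs6, a signalling suppressor, 1.52-fold lower.

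In all, 85 of 15767 genes passed an edgeR adjusted p of 0.05, 39 higher and 46 lower, and 42 of them changed at least 1.5-fold. In all 85 the groups did not overlap; this also held for 38.2% of all tested genes. Further named rises were Ece1, Dhcr7, Gcat, E2f5, Atp5b and Hmga1, of which Dhcr7 was the largest at 1.63-fold. Further named falls were Vegfa, Mmp13, Atp6v0d2, Clec4n, Bmp2, Tgm2 and Src, of which Src was the smallest at 1.88-fold. Rn18s-rs5, a ribosomal RNA sequence, was 1.97-fold lower (574 ± 24.7 CPM, SD, n = 3, against 1129 ± 270.4 CPM, SD, n = 2). It had 810 ± 159.6 CPM (SD, n = 2) in the scramble group and 606 ± 67.4 CPM (SD, n = 3) in the sponge group. The libraries were made from polyadenylated RNA, so this ribosomal count is not read as an effect of the vector.

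The count of 85 depended on single libraries. It was 0 without replicate 1 and 0 without replicate 2 of the mutated control, 6 without overexpression replicate 2 and 279 without overexpression replicate 3. It was 24 without either scramble library, 31 without sponge replicate 1, 143 without sponge replicate 2 and 252 without sponge replicate 3. DESeq2 called 500.

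The mutated control was apart from the other 3 groups for part of these genes. Slc7a11 had 19.0 ± 4.71 CPM (SD, n = 2) in the scramble group and 12.8 ± 1.43 CPM (SD, n = 3) in the sponge group. Against the scramble group, a comparison added after seeing the data, edgeR called 7 genes. There the log2 fold change of Slc7a11 was −0.36 (SE 0.17, edgeR adjusted p = 0.383), that of Ece1 0.10 (SE 0.08) and that of the fatty acid receptor Cd36 0.04 (SE 0.06). Il6 and Cd86 did not pass there either, with −1.04 (SE 0.27) and −0.51 (SE 0.11) and edgeR adjusted p-values of 0.194 and 0.165. Their direction was the same, but the size of their falls and their calls depend on the control. Klf2, Ccl2, Ccl7 and Socs6 passed there, with log2 fold changes of 1.17, 1.47, 1.81 and −0.49. Wasl, Ednrb and Tnf had −0.52, −0.71 and 1.37, with edgeR adjusted p-values of 0.0896, 0.0991 and 0.0903. The mutated control itself lay above the scramble group for Ccl2 (177 ± 6.45 against 111 ± 1.11 CPM, SD, n = 2 each). The same held for Ccl7 (53.7 ± 5.4 against 31.3 ± 3.0 CPM, SD, n = 2 each). The scramble vector is a sponge vector, so this comparison does not separate the microRNA from the type of vector.

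Genes of sterol synthesis and uptake rose with overexpression (camera adjusted p = 5.86e-10), with 21 of 23 tested members above 0 and a median log2 fold change of 0.42. The adjusted p was 0.515 with an estimated correlation. Adjusted over the list alone, 15 rose and 1 fell, and over all genes tested only Dhcr7, an enzyme of cholesterol synthesis, passed. The gene that fell was Scd1, a fatty acid desaturase, at 0.347 ± 0.0726 CPM (SD, n = 3) with overexpression. Idi1, an isomerase of the same pathway, had 0.42 (SE 0.11). Glycolysis and hypoxia genes rose by a median of 0.24 (camera adjusted p = 0.000125; adjusted p = 0.596 with an estimated correlation). In that list 9 rose and Vegfa, a growth factor, fell, adjusted over the list alone; over all genes only Vegfa passed. Against the scramble group both lists also rose, with camera adjusted p-values of 1.17e-15 and 4.4e-08; the adjusted p was 0.257 and 0.336 with an estimated correlation.

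Cell cycle genes rose by a median of 0.08 (camera adjusted p = 0.000164; adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone 9 of 30 rose; Aurkb, a mitotic kinase, and Rrm2, a ribonucleotide reductase subunit, passed over all genes tested. Oxidative phosphorylation genes rose by a median of 0.09 (camera adjusted p = 0.00581; adjusted p = 0.849 with an estimated correlation). In that list 2 of 25 rose adjusted over the list alone, and Atp5b, an ATP synthase subunit, passed over all genes. Type I interferon response genes rose by a median of 0.14 (camera adjusted p = 1.27e-05; adjusted p = 0.515 with an estimated correlation). Of 34 tested, 27 were above 0, 4 rose adjusted over the list alone, Mx2 and Usp18 among them, and Ifit1 passed over all genes. The oxidative phosphorylation call ended without overexpression replicate 1 (camera adjusted p = 0.285); the other 4 calls passed with any 1 library left out. Against the scramble group the interferon list fell (camera adjusted p = 0.00274; adjusted p = 0.441 with an estimated correlation). The oxidative phosphorylation and cell cycle lists rose there too, with camera adjusted p-values of 0.0221 and 0.049; the adjusted p was 0.666 and 0.441 with an estimated correlation.

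The inflammatory list did not pass as a whole (camera adjusted p = 0.747): over all genes 3 of 30 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell. Against the scramble group the inflammatory list rose (camera adjusted p = 0.000555; adjusted p = 0.374 with an estimated correlation), so its call depends on the control. In the glutathione, NRF2 and iron list 1 of 27 rose and 6 fell adjusted over the list alone, among them Slc7a11, Srxn1 and Gclm, and Slc7a11 passed over all genes (camera adjusted p = 0.0809). Its median was 0.01 while the test pointed down. In the lipid-associated macrophage list 1 of 19 rose and 4 fell adjusted over the list alone, and Cd36 and the protease Mmp12 fell over all genes (camera adjusted p = 0.0601). In the alternative activation list 2 of 18 rose and 6 fell adjusted over the list alone, and the chemokine Ccl24 fell over all genes (camera adjusted p = 0.134).

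The remaining lists did not pass with camera against the mutated control. Adjusted over the list alone, 3 of 31 Kupffer cell and macrophage identity genes rose and 6 fell, 0 over all genes (camera adjusted p = 0.284). Of 24 integrated stress genes 1 rose and 2 fell, 0 over all genes (camera adjusted p = 0.284). Of 19 antigen presentation genes (camera adjusted p = 0.233) and 20 microRNA pathway genes (camera adjusted p = 0.195), 0 passed by either adjustment. Of 15 matrix and protease genes 4 rose and 5 fell adjusted over the list alone; over all genes Adam8 and Tgfbi rose and Mmp13 fell (camera adjusted p = 0.767). Of 22 immediate early genes 1 rose and 2 fell adjusted over the list alone, and Klf2 rose over all genes (camera adjusted p = 0.28). Of 7 endothelial and stellate genes, Kdr, an endothelial receptor, fell by either adjustment (camera adjusted p = 0.157). Of 3 hepatocyte genes Ass1 rose adjusted over the list alone (camera adjusted p = 0.787), and Cd4 alone was tested of the lymphocyte, neutrophil and erythroid list (camera adjusted p = 0.747), too few for a statement on a list.

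Against the scramble group 6 of these lists passed, 1 of them the lymphocyte list with its single tested gene, Cd4 (camera adjusted p = 0.0151; adjusted p = 0.257 with an estimated correlation). Integrated stress, immediate early and matrix lists rose, with camera adjusted p-values of 1.07e-06, 8.45e-05 and 0.0389; the adjusted p was 0.441, 0.356 and 0.257 with an estimated correlation. Antigen presentation and endothelial lists fell, with camera adjusted p-values of 0.0248 and 0.0385; the adjusted p was 0.558 and 0.257 with an estimated correlation.

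**Figure D2:**
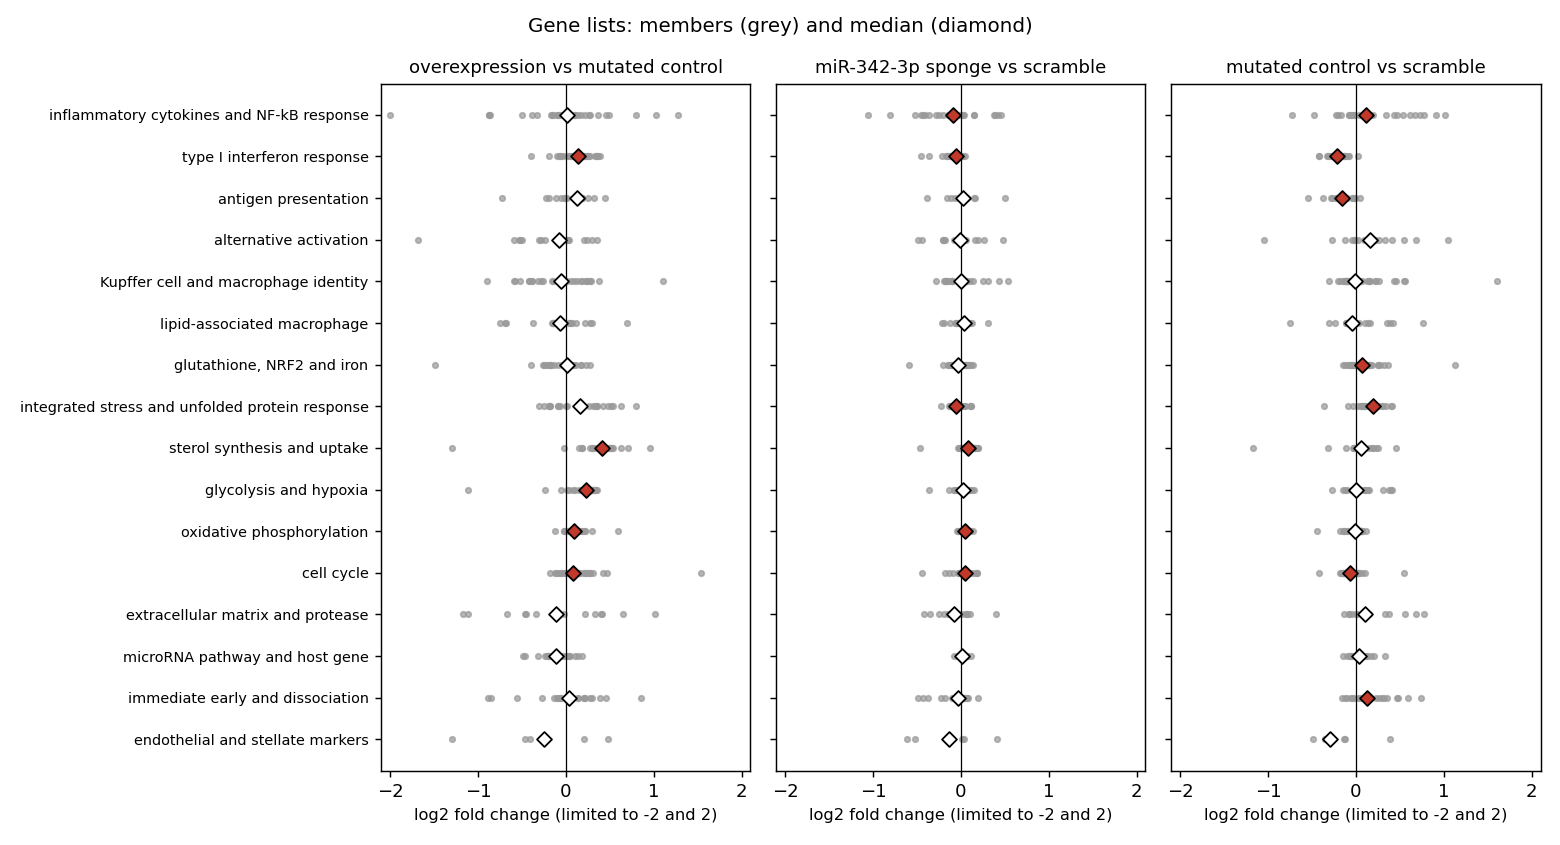
Log2 fold change (x axis, limited to a size of 2) of each list member (grey points) and list median (diamonds) in 3 comparisons, for the 16 lists drawn. Filled diamonds mark a camera adjusted p under 0.05 at the preset correlation, and the sterol list has the highest median, 0.42, with overexpression.

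The next question was whether genes with miR-342-3p sites moved. The 1847 tested genes with an 8mer or 7mer-m8 site lay lower with overexpression than the 10240 without, with mean log2 fold changes of −0.06 against 0.00. The camera adjusted p over the 2 vector comparisons was 0.00196; the adjusted p was 0.269 with an estimated correlation. UTRs of site genes were longer, with a median of 2559 bases against 956, and fold changes fell with UTR length across genes (Spearman rho −0.275; genes are not independent replicates). Against genes matched on UTR length the call ended and the difference of the means turned from −0.06 to 0.000353 (adjusted p = 0.898). It also ended without overexpression replicate 1 (adjusted p = 0.079), and with the scramble control in place of the mutated control, where the difference was −0.03 (camera adjusted p = 0.0808). Between the controls site genes had a mean of 0.04 in the mutated control against 0.00 for the others, which did not pass (camera adjusted p over 3 comparisons = 0.0717). The seed match GTGTGAG ranked 2658 from the lowest among 16384 7-mers (coefficient −0.02, z = −3.18). Ranking by coefficient takes no account of how many genes hold a 7-mer, so rare 7-mers can fill both ends. By z in the wider model, added after seeing the data, it ranked 1956 of 16113 (z = −1.26).

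For the 575 genes with an 8mer the camera adjusted p was 1.86e-05; the adjusted p was 0.201 with an estimated correlation. It was 0.125 against length-matched genes, a test added after seeing the data. With the scramble control in place it was 0.00214 at the preset and 0.404 with an estimated correlation. Of 43 lower genes with a UTR, 8 had an 8mer, against 567 of 12044 other genes (Fisher's exact test, two-sided, p = 0.000828). With log UTR length as a covariate the odds ratio was 3.55 (95% interval from 1.58 to 8.002). This count was made after the genes had been seen, and genes are not independent replicates. Named genes were Wasl (8mer at base 285 of a UTR of 2480 bases), Socs6 (113 of 4019), Ednrb (119 of 2441), the histone gene H2aw (669 of 1700) and Slc7a11 (6981 of 7364). Against the mean of the scramble and sponge groups, Slc7a11 had −0.07 with overexpression (edgeR adjusted p = 0.815). In the mutated control it had 1.42 there (edgeR adjusted p = 0.00488), so its fall rests on that control. Wasl, Socs6, Ednrb and H2aw had −0.53, −0.55, −0.76 and −0.50 with overexpression there, each with an edgeR adjusted p under 0.05. Sites of the other arm, miR-342-5p, gave an adjusted p of 0.217.

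The sponge against the scramble sponge asked what a sponge meant to sequester miR-342-3p changes. The mature microRNA was not measured here, so whether the sponge reduced it is not known. Inflammatory genes fell as a list, by a median of −0.09 (camera adjusted p = 0.000657; adjusted p = 0.524 with an estimated correlation). Of 30, 2 fell adjusted over the list alone, Acod1, the itaconate-producing enzyme (−0.37, SE 0.08), and Il6 (−1.05, SE 0.27), and 0 over all genes. Il6 had 1.60 ± 0.475 CPM (SD, n = 3) with the sponge and 1.63 ± 0.187 CPM (SD, n = 3) with overexpression. It thus fell in both comparisons, each against its own control, so its fall does not separate the opposite perturbations from the controls. The interferon list fell by a median of −0.05, with 5 of 34 above 0 (camera adjusted p = 5.62e-05; adjusted p = 0.524 with an estimated correlation). The integrated stress list fell by a median of −0.05 (camera adjusted p = 0.0393; adjusted p = 0.765 with an estimated correlation). Sterol, oxidative phosphorylation and cell cycle lists rose by medians of 0.08, 0.05 and 0.04. Their camera adjusted p-values were 0.0242, 0.0172 and 0.0361; the adjusted p was 0.763, 0.763 and 0.524 with an estimated correlation. Outside the inflammatory list 0 members of these lists passed by either adjustment. The other 12 lists did not pass; in them only Il1rn, of the alternative activation list, passed adjusted over the list alone.

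Single libraries ended 5 of the 6 sponge calls; the interferon list passed with any 1 library left out. Without scramble replicate 2 the inflammatory, integrated stress, oxidative phosphorylation and cell cycle calls ended (camera adjusted p-values of 0.0679, 0.882, 0.866 and 0.882). Without sponge replicate 1 the integrated stress, sterol and cell cycle calls ended (0.12, 0.182 and 0.0587). Without sponge replicate 3 the sterol, oxidative phosphorylation and cell cycle calls ended (0.591, 0.846 and 0.226). The sterol call ended without scramble replicate 1 (0.725). The integrated stress list turned to a rise without sponge replicate 2 (camera adjusted p = 0.037; adjusted p = 0.758 with an estimated correlation). Its call also ended without either mutated control library (0.0502 and 0.06) or overexpression replicate 2 (0.0668).

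No gene passed an edgeR adjusted p of 0.05 for the sponge, against 368 genes at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0. Of the 5 genes with the smallest p, none passing, ENSMUSG00000120024 rose (0.64, SE 0.12). The others fell: Gm19410 (−1.16, SE 0.25), Clec4e, a lectin receptor (−0.27, SE 0.06), Slc15a3, a transporter (−0.29, SE 0.06), and Acod1. Slc7a11 had −0.59 (SE 0.17) and Evl 0.04 (SE 0.08). Genes with a miR-342-3p site did not separate from the others (camera adjusted p = 0.539). By coefficient GTGTGAG ranked 10447 from the highest among 16384 7-mers (z = −0.288). The 575 genes with an 8mer had a mean of −0.01, as had the others. The rule named those above 0 with the smallest p, none passing, among them Impa2 with 0.14 (SE 0.07), Eif4ebp2 with 0.16 (SE 0.08) and Socs6 with 0.11 (SE 0.06).

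Overexpression replicates 1 and 2 and sponge replicate 3 had positive positions on the first principal component, 39.1, 14.96 and 21.1; the next library, scramble replicate 1, lay at −2.70. They had the lowest shares of counts in genes annotated as TEC, antisense or lincRNA, 0.461%, 0.517% and 0.464%. Without all 3, a setting added after seeing the data that leaves 1 overexpression library, edgeR called 133 genes for overexpression, and 54 of the 85 were called again. Without only overexpression replicate 1 and sponge replicate 3, also added, edgeR called 756, and 79 of the 85 were called again in the same direction. With that pair left out the oxidative phosphorylation call ended with overexpression (camera adjusted p = 0.167), while the sterol, glycolysis, cell cycle and interferon lists still rose. The lipid-associated macrophage and glutathione lists then fell (camera adjusted p-values of 0.000682 and 0.00238). For each of these 6 lists the adjusted p was 0.36 with an estimated correlation. For the sponge the sterol, oxidative phosphorylation and cell cycle calls ended (camera adjusted p-values of 0.59, 0.599 and 0.0953), with medians turned to −0.04 and −0.01 for the first 2, and the inflammatory, interferon and integrated stress lists still fell. The glutathione list and the glycolysis list then fell and the microRNA pathway list rose (camera adjusted p-values of 2.86e-05, 0.0337 and 2.86e-05). With an estimated correlation the adjusted p was 0.774 for glycolysis, 0.426 for integrated stress and 0.344 for the inflammatory, interferon, glutathione and microRNA pathway lists.

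**Figure D3:**
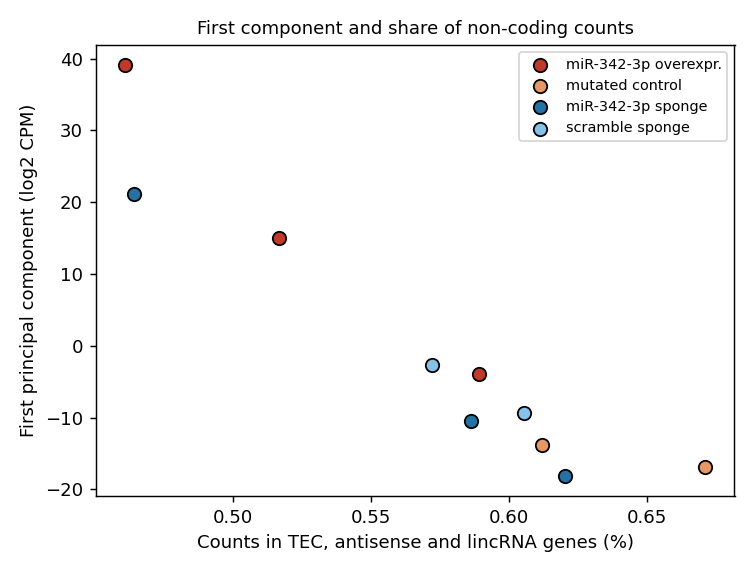
First principal component of log2 CPM (y axis) against the percent of counts in TEC, antisense and lincRNA genes (x axis), 1 point per library, coloured by vector group. Overexpression replicates 1 and 2 and sponge replicate 3 have the highest positions and the lowest shares.

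The 2 control vectors were compared as a background. Interferon response genes were lower in the mutated control than in the scramble control, with 1 of 34 above 0 and a median of −0.21 (camera adjusted p = 1.24e-22; adjusted p = 0.142 with an estimated correlation). Adjusted over the list alone 16 fell, and 0 over all genes. Antigen presentation genes fell by a median of −0.16 (camera adjusted p = 1.65e-05; adjusted p = 0.298 with an estimated correlation). Inflammatory, glutathione and integrated stress lists rose by medians of 0.11, 0.07 and 0.20. Their camera adjusted p-values were 0.000331, 9.34e-05 and 6.12e-05; the adjusted p was 0.313, 0.298 and 0.488 with an estimated correlation. Adjusted over the list alone 7 inflammatory genes rose and 1 fell, Il6 and Ccl2 among those that rose, and 6 glutathione and 3 integrated stress genes rose, 0 of them over all genes. Immediate early genes rose (camera adjusted p = 0.0033; adjusted p = 0.415 with an estimated correlation), with 0 members passing. Cell cycle genes fell (camera adjusted p = 0.00992; adjusted p = 0.313 with an estimated correlation), with 1 of 30, Aurkb, passing adjusted over the list alone. The hepatocyte list had 3 tested genes (camera adjusted p = 0.0253; adjusted p = 0.284 with an estimated correlation), of which Ass1 fell adjusted over the list alone. The lymphocyte, neutrophil and erythroid list had 1 tested gene, Cd4 (1.36 ± 0.0247 CPM, SD, n = 2, against 2.04 ± 0.0235 CPM, SD, n = 2), so nothing is said of that list. By gene, edgeR called 4 of 15767: Mir342 was higher, and Lilra6 (−0.87, SE 0.10), Pira12 (−0.82, SE 0.09) and the interferon-inducible GTPase Tgtp2 (−0.49, SE 0.07) were lower. Lilra6 and Pira12 belong to a family of closely related receptor genes, so their counts are uncertain. DESeq2 called 90 and limma-voom 4. With only the 2 control groups in the fit, edgeR called 574. In settings added after seeing the data, it called 398 with 1 surrogate variable and 271 without overexpression replicate 1 and sponge replicate 3. With either numbering as a replicate block it called 1. The count of 4 thus depends on the fit and does not show that the 2 controls are alike. The edgeR count was 0 without scramble replicate 2, 36 without overexpression replicate 1 and 9 without overexpression replicate 3, 1 without scramble replicate 1 or either mutated control library, and 2 without sponge replicate 1 or sponge replicate 2.

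The overexpression and sponge effects had a correlation across genes of 0.0807 (Pearson) and 0.117 (Spearman); genes are not independent replicates. Pearson's r was −0.137 without sponge replicate 3, −0.0171 without scramble replicate 2, 0.245 without sponge replicate 2, 0.139 without sponge replicate 1 and 0.0306 without mutated control replicate 2. No gene passed the edgeR test of the difference of the 2 effects, against 1271 at an unadjusted p under 0.05. DESeq2 called 48 and limma-voom 0. With edgeR 7 passed without sponge replicate 3 and 331 without a filter. In 2 settings added after seeing the data, 158 passed with 1 surrogate variable and 271 without overexpression replicate 1 and sponge replicate 3. The smallest p-values were for Hpse, a heparanase (−0.77, SE 0.09), Socs6 (−0.71, SE 0.09), Wasl (−0.85, SE 0.11), Gpr157 (−0.81, SE 0.11) and Ednrb (−1.35, SE 0.19), none passing.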

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

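The tests of the 2 patterns weighed here were chosen after the results had been seen. For 7 gene lists the effect of overexpression differed from that of the sponge in a camera test of the difference, at the preset correlation. The adjusted p-values were 1.15e-10 for the interferon response, 9.84e-06 for sterol synthesis, 0.00113 for glycolysis and hypoxia and 0.0234 for lipid-associated macrophage genes. They were 0.0311 for the cell cycle, 0.039 for inflammatory genes and 0.0399 for the integrated stress response. The difference was above 0 for 34 of 34 interferon genes and 22 of 23 sterol genes. With an estimated correlation the adjusted p-values of these 7 lists were between 0.686 and 0.755. Each effect was measured against its own control vector, so this difference also holds the difference between the controls, in which the interferon list had a median of −0.21.

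For 48 of the 85 genes called with overexpression the mutated control lay farther than the overexpression group from the mean of the scramble and sponge groups, and for 37 it was the other way. The share was 56.5% (95% exact interval from 45.3% to 67.2%, counting error only), against 46.2% of all genes. Against that mean, edgeR called overexpression in the direction of the effect for 27 of the 85 genes, Klf2, Tnf and Socs6 among them. It called the mutated control in the opposite direction for 20 others, Slc7a11 and Ece1 among them. The 85 had been chosen for their difference between the same overexpression and mutated control libraries. That choice favours departures on both sides, so these counts do not decide whether either group alone is the cause. Over all tested genes, in either direction, the same tests called 196 genes for overexpression and 36 for the mutated control. For 38 of the 85 neither passed in these directions, which leaves those open. Without the 3 libraries with positive positions on the first principal component 54 of the 85 were called and the median effect kept 88.4% of its size; with 1 overexpression library left, this does not decide whether those libraries contribute.

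Overexpression replicates 1 and 2 and sponge replicate 3 had positive positions on the first principal component, which held 31.1% of the variance. Their shares of counts in genes annotated as TEC, antisense or lincRNA were 0.461%, 0.517% and 0.464%, against 0.572% to 0.671% in the other 7, so 3 of the 3 lay outside that range. A candidate explanation is a lower content of unspliced or nuclear RNA. The tables argue against depth: with all libraries thinned to the total of the shallowest, these 3 stayed apart from the other 7 in 10 of 10 draws. No biological explanation was tested, and 2 of the 3 carry the overexpression vector.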

How the results depend on the processing

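The surrogate variable, other controls, exclusion of the joined-field pair or of 2 or 3 libraries by the first principal component, and the length-matched 8mer test were chosen after seeing the data. The causes of these changes were not tested. Genes changed with overexpression, with the sponge, between the controls and in the difference numbered 500, 1, 90 and 48 with DESeq2, 1390, 24, 149 and 331 without a filter, and 479, 4, 398 and 158 with 1 surrogate variable. Without overexpression replicate 1 and sponge replicate 3, overexpression gave 756 and the controls and the difference 271 each; without these and overexpression replicate 2 the counts were 133, 3, 445 and 77. With only the 2 groups compared, overexpression gave 34 and the controls 574; overexpression gave 42 at 1.5-fold and 7 with the scramble control in place. The sponge gave 49 against the mutated control, and the controls gave 1 without the joined-field pair. RLE factors, library size only, the stricter filter and limma-voom left the overexpression count between 81 and 93.

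With either numbering as a replicate block, overexpression gave 0 genes and the controls 1. Deviations from the group means correlated between −0.414 and 0.156 in same-numbered libraries. In a group of 2 libraries these deviations mirror each other, so the correlations cannot decide whether the numbers pair the samples. Leaving out 1 library gave 0 to 279 genes for overexpression, 0 to 0 for the sponge, 0 to 36 for the controls and 0 to 7 for the difference. Lists ranged from 5 to 8 for overexpression and from 3 to 9 for the sponge, the correlation from −0.137 to 0.245, and unadjusted seed-site p-values from 0.000198 to 0.0395 for overexpression and from 0.103 to 0.566 for the sponge. Adjusted over the 2 comparisons, the highest for overexpression was 0.079, without its replicate 1, which ends that call. Where a group keeps 1 library, it is assumed to vary like the others.

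The correlation of the effects was 0.00703 without a filter, 0.175 with the stricter filter and −0.0797 without the joined-field pair. With an estimated correlation 0 lists passed for overexpression and 0 for the sponge, and fry gave 2 and 0. The 2 were the cell cycle list, which rose, and the endothelial and stellate list, which fell (fry adjusted p = 0.0293 for each). The sterol list did not pass with fry (fry adjusted p = 0.200). With the scramble control in place 12 lists passed for overexpression, and without the 3 libraries 8 passed for overexpression and 6 for the sponge. The unadjusted seed-site p for overexpression was 0.108 with miR-342-5p sites, 0.135 with an estimated correlation, 0.719 with length matching, where the difference turned to 0.000353, and 0.0624 for length-matched 8mers. For the sponge the direction turned with the library-name replicate block (0.724), length matching (0.898), length-matched 8mers (0.977), without the joined-field pair (0.823), without overexpression replicate 1 and sponge replicate 3 (0.0597), without scramble replicate 2 alone (0.503) and without sponge replicate 3 alone (0.143).

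Of 3079 alternative values of named genes, 2604 kept direction and side of the threshold, 348 no longer passed, 105 newly passed and 22 changed sign. With the scramble control in place, overexpression values were −0.0628 for Ifit1, −0.0444 for Tap1, −0.102 for H2-Ab1, 0.0448 for Cd36, 0.0654 for Lpl, 0.0382 for Hspa5 and −0.152 for Ass1. Sponge values were −0.0411 for Dhcr7, −0.12 for Fdps and 0.0843 for Trf without the joined-field pair, and 0.0186 for Trf without the other pair. Leaving out 1 library, overexpression values ranged from −0.0946 to 0.0396 for Evl and from −0.900 to 0.0708 for Apoa2. Sponge values ranged from −0.00947 to 0.0802 for Evl, −0.787 to 0.0395 for Apoa2, −0.106 to 0.0454 for Trf, −1.05 to 0.00782 for Pecam1 and −0.102 to 0.894 for Pdgfrb.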

Other observations

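The tests of the GCAGGCC 7-mer for an A after the site were chosen after the result was seen; those of base composition and of B1 repeats were set before they were run. With overexpression, in the macrophage identity list the iron exporter Slc40a1 fell by 0.52 on the log2 scale and the transcription factor Cebpa fell by 0.42, while Id1 rose by 1.11 at a low level (1.30 ± 0.32 CPM, SD, n = 3), adjusted over the list alone. In the matrix and protease list Adam8 and Tgfbi rose by 0.40 and 0.42 and Mmp13, a collagenase, fell by 1.11, over all genes tested. The immediate early genes Fos and Fosb fell by 0.56 and 0.89 adjusted over the list alone. With the sponge, Il1rn, the interleukin-1 receptor antagonist, fell by 0.44 adjusted over the list alone and did not pass over all genes.

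A 7-mer was found by looking. The 4 comparisons were scanned in both directions, and with the wider model GCAGGCC was the lowest of 16113 7-mers in the mutated control against the scramble control (z = −6.55, coefficient −0.04, 1336 genes with it). With the covariates fixed beforehand it ranked 55 of 16384 by coefficient, which is not comparable with a rank by z. A candidate explanation is that the mutated hairpin acts through a seed of its own; its sequence is not given in the sources used here. With the libraries parted, GCAGGCC ranked 1 of 16113 both in mutated control replicate 1 against the scramble libraries and in replicate 2 against the sponge libraries, although both replicates had been part of the scan; with the covariates fixed beforehand it ranked 31 and 52 of 16384. A seed would favour an A after the site. With A the mean differed by −0.03 in the first part (1-sided permutation p = 0.0001, the smallest that 10000 permutations can give). In the second part it differed by −0.02 (permutation p = 0.0756), which leaves this open. The permutations shuffled genes, which are not independent replicates, and each part held 1 mutated control library. Their p-values therefore measure no spread between libraries. For base composition, z lay 5.97 standard deviations below the mean of the 126 7-mers with the same bases. GCAGGCC had been picked as the lowest of all 7-mers, so it had to lie below them, and this distance does not decide. Those 7-mers had a mean z of −0.33 and a lowest z of −3.73, so the same bases in another order were shifted little on average. Without the 1453 genes that hold a B1 fragment 105.5% of the coefficient was kept, which argues against B1 repeats with these exact fragments. Repeats that differ from them stayed in and are left open. CCCAGCA, part of 1 fragment searched, ranked 2 of 16113 from the lowest in the same scan (z = −4.67).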
